A study of mouse gut metagenome with 48 samples.

How the data were processed

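Faecal DNA of C57BL/6 mice was extracted with a soil DNA kit and bead beating and sent to a company for 16S rRNA sequencing, per the labels' protocols, although the labels give the tissue as colon. The submitters' processing notes name FastQC. The 16S region, the read processing, the taxonomy database and the number of reads per sample are not given in the sources used here. Depth is therefore unknown, and no counting interval or detection limit is given. Samples were grouped by arm and week from their titles, as vehicle at week 0 (13 samples), EpOME at week 0 (11), vehicle at week 9 (13) and EpOME at week 9 (11). The labels give no batch, cage, sex or dose. If each week was sequenced in a run of its own, week and run cannot be told apart.

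The authors deposited a phylum table and a genus table that hold group summaries only. Per the file headers, each table gives the group mean of relative abundance, and these means are in percent, since each column summed to 100. The deposited SD columns are in percentage points and their number of samples was taken from the labels. The tables' control columns were taken to be the vehicle arm. The deposited p-values compare the arms at week 0 and at week 9 per the file headers, with no test named. They equalled a two-sided Student's test with equal variances on the deposited means and SDs with 13 and 11 samples, for all 9 rows of the phylum table and all 52 rows of the genus table at both weeks, within a relative tolerance of 1e-06. This check also bears on the group sizes. Each table has a row named for taxa under 0.1%, called the pooled row here, which left 8 phyla and 51 genera to test. How the authors defined that row is not stated.

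The tests fixed before the data were examined needed values per sample, which the tables do not hold, and were replaced. They were permutation tests of log2 relative abundance, comparisons of community distance, and tests of the Shannon index. In their place, each taxon was tested with a two-sided Welch's test computed from the deposited means, SDs and group sizes, on relative abundance with no log and no pseudocount. The interaction was the change from week 0 to week 9 in EpOME minus that in vehicle, with Satterthwaite degrees of freedom over the 4 groups. All samples were treated as independent, since no pairing could be used. Benjamini-Hochberg adjustment ran over the 8 phyla or the 51 genera of a comparison, with a threshold of 0.05. Ratios of means carry 95% confidence intervals from the delta method, which are rough where an SD is near or above its mean. For the ratio of Firmicutes to Bacteroidetes, the SD assumed the correlation that makes it largest, and its p-values were adjusted over 5 comparisons. The interaction of that ratio and of the lists was added after the tables were seen.

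Before the data were examined, 9 genus lists were fixed. Of these, 6 had a member in the table: producers of butyrate and other short-chain fatty acids (13 members), mucin degraders (4), lactic acid bacteria (1), genera linked to colitis or colorectal tumours (4), Erysipelotrichaceae (3) and Bacteroidales of the mouse gut (4). The other 3 had no member listed and were not tested: Enterobacteriaceae, sulfate reducers, and food or reagent contaminants. A genus can be in several lists. The SD of a list's sum was taken as the sum of its members' deposited SDs, the largest value any correlation allows, so these tests are conservative. List p-values were adjusted over the 6 lists. Genera were placed in phyla from general knowledge of their taxonomy, since the genus table does not give the phylum.

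Taxa were named by a rule fixed at the same time. It took phyla with a mean of 1% or more in any group, the 10 genera with the highest mean over all samples, and genera past the threshold. The last were limited to 15 at week 9, 8 in the interaction and 4 per direction elsewhere, by largest log2 ratio. Members of a described list averaging at least 0.1% were also named.

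The alternative fixed beforehand that could still be run left out taxa with a mean under 0.1%. Alternatives added after the tables were seen were Student's test, a lognormal approximation that converts each mean and SD to the log2 scale, the same with limma's variance moderation, the pooled row counted as a taxon, a correlation of 0.5 between weeks, and independent list members. The Welch, Student and lognormal procedures were tested on simulated samples for the 51 genera of the week 9 comparison, over 250 simulations with changes and 250 without. Both arms were drawn from the vehicle group's week 9 means and SDs, with genera independent. The EpOME group's SDs were not simulated, and they were larger relative to the means (median ratio of SD to mean 0.745 against 0.616). Of genera lowered 1.5-fold, 2-fold and 4-fold, 8 at each fold, Welch's test recovered 20.55%, 51.65% and 86.1% with lognormal values. These shares hold for that many changed genera and need not hold for the observed comparison. Welch's test gave an unadjusted p under 0.05 for 4.02% of unchanged genera. The lognormal approximation did so for 7.32% of them, or 9.47% when the simulated values followed a gamma distribution. Intervals of the Firmicutes interaction held the true value in 94.95% of 2000 simulations. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.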

Results

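Bacterial communities of the mouse gut were profiled by 16S rRNA gene sequencing of DNA from faecal samples of C57BL/6 mice. The mice were given azoxymethane, a colon carcinogen, and dextran sulfate sodium, which injures the colonic lining, a combination used to induce colon tumours. Whether the week 0 samples were taken before or after these treatments is not known here. The labels place the samples in a vehicle arm or in an arm given 12,13-EpOME, an epoxide that cytochrome P450 monooxygenases make from linoleic acid. The 48 samples comprised 13 vehicle and 11 EpOME samples labelled week 0, and 13 vehicle and 11 EpOME samples labelled week 9. The labels do not state when dosing began, how the weeks were counted, or whether a number at both weeks marks the same mouse. Values are the authors' deposited group means of relative abundance, in percent of the community, with the deposited SD given at a group's main values. The tables listed 8 phyla and 51 genera, and each also held 1 row for the taxa under 0.1%, whose exact content is not stated. The number of reads per sample is unknown, so precision is stated only through the deposited SDs and the group sizes in the labels. No values per sample were used here, so the number of samples showing each direction is not given. Nothing in the labels says that samples of a group came from separate cages, and p-values measure only the spread between these samples.

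The week 9 comparison asked whether mice given the epoxide carried a different gut community from mice given vehicle. Firmicutes, the phylum of 40 of the 51 listed genera, were lower with EpOME, at 40.0% (deposited SD 6.66) against 49.6% (SD 8.36). The difference was -9.64 percentage points (95% CI -16.0 to -3.27, adjusted p = 0.0222 by Welch's test with Benjamini-Hochberg adjustment over 8 phyla). Bacteroidetes, the other main phylum, were higher, at 53.8% (SD 10.6) against 43.0% (SD 9.10), a difference of 10.8 points (95% CI 2.29 to 19.2, adjusted p = 0.0412). Deferribacteres, represented by the mucus-dwelling genus Mucispirillum, averaged 0.0218% (SD 0.0224) with EpOME and 0.0641% (SD 0.0422) with vehicle. Their ratio of means was 0.340 (95% CI 0.168 to 0.688, adjusted p = 0.0222), and this phylum was named after its values were seen. The ratio of Firmicutes to Bacteroidetes means was 0.744 with EpOME and 1.15 with vehicle, a log2 difference of -0.63 (95% CI -1.09 to -0.18, adjusted p = 0.0107 over 5 comparisons). Verrucomicrobia, here almost entirely the mucin degrader Akkermansia, averaged 4.07% (SD 7.18) with EpOME and 5.55% (SD 6.79) with vehicle and did not pass the test (adjusted p = 0.613). Actinobacteria averaged 1.48% (SD 1.19) and 1.05% (SD 0.548) and did not pass either (adjusted p = 0.466). In all, 3 of 8 phyla passed, 1 higher and 2 lower. With phyla averaging under 0.1% left out, Firmicutes alone passed, since Deferribacteres were removed and Bacteroidetes reached an adjusted p of 0.0540 (0.0319 to 0.0540 over all alternatives).

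**Figure D1:**
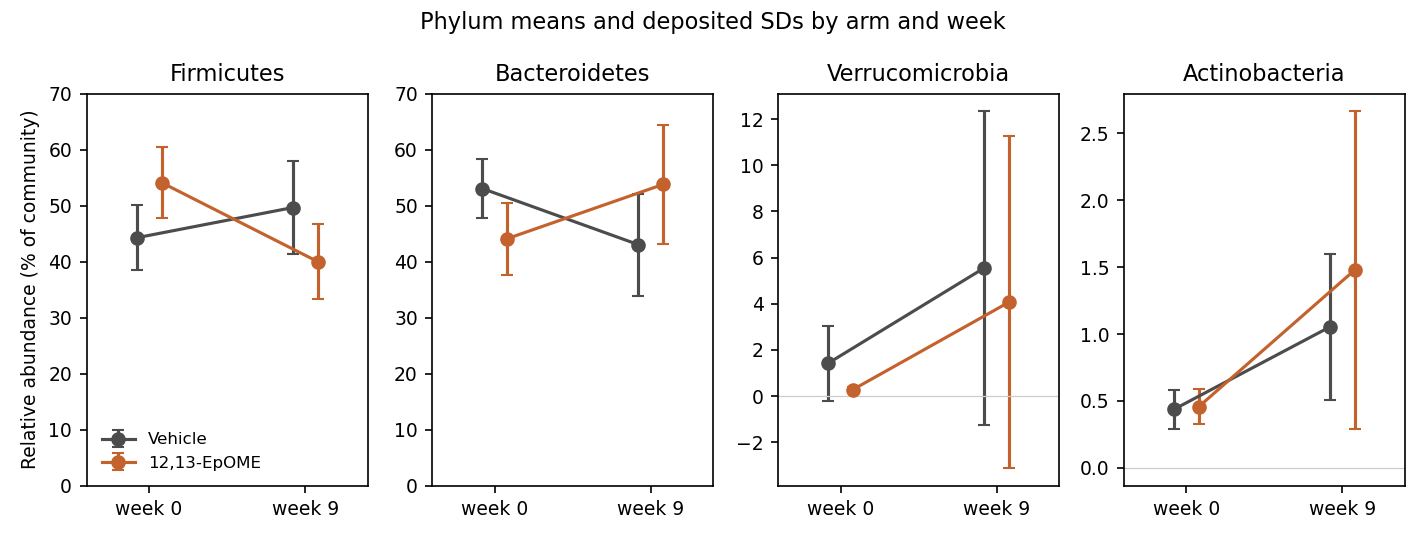
Relative abundance in percent of the community (y axis) at weeks 0 and 9 (x axis) for the 4 phyla that reached 1% in any group, with vehicle in grey and 12,13-EpOME in orange. Points are the authors' group means and bars are the deposited SDs, which reach below 0 where the SD exceeds the mean. Firmicutes went from 54.1% to 40.0% with EpOME and averaged 44.2% and 49.6% with vehicle.

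No single genus separated the arms at week 9 after adjustment (0 of 51 by Welch's test, smallest adjusted p = 0.132; 0 by Student's test). At an unadjusted p under 0.05, 10 genera differed, 9 lower and 1 higher with EpOME, where 2.55 would be expected by chance. Butyricicoccus, a butyrate producer, averaged 0.0638% (SD 0.0240) with EpOME and 0.137% (SD 0.0806) with vehicle, a ratio of 0.466 (95% CI 0.315 to 0.687). Mucispirillum had a ratio of 0.340, Lachnospiraceae UCG-001 of 0.426, Ruminococcaceae UCG-003 of 0.175 and Clostridium sensu stricto 1 of 0.526. Lachnospiraceae UCG-006, ASF356, Anaerotruncus and Ruminococcaceae UCG-009, named after their values were seen, had ratios of 0.313, 0.473, 0.602 and 0.540. Muribaculum, a genus of the Bacteroidales, averaged 2.74% (SD 1.51) against 1.59% (SD 0.621), a ratio of 1.72 (95% CI 1.16 to 2.53). Among the most abundant genera, Lactobacillus averaged 19.7% (SD 6.77) with EpOME and 22.5% (SD 9.58) with vehicle, and unclassified Muribaculaceae 8.37% (SD 6.96) and 4.50% (SD 2.38), and neither passed (adjusted p = 0.578 and 0.311). In the authors' deposited table, 10 genera had a p under 0.05 at week 9, and 0 remained after Benjamini-Hochberg adjustment. A lognormal approximation of log2 values called 6 genera, all lower with EpOME, but it called unchanged genera too often in simulations. Those simulations used the vehicle group's SDs for both arms. These 6 were Butyricicoccus, Mucispirillum, ASF356, Lachnospiraceae UCG-001, Lachnospiraceae UCG-006 and Ruminococcaceae UCG-003.

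**Figure D2:**
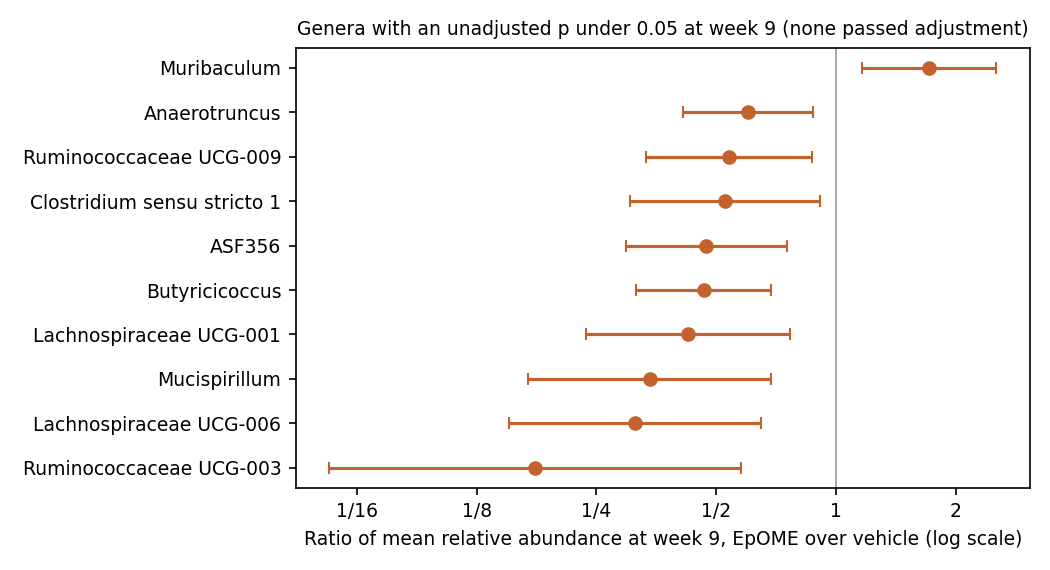
Ratio of mean relative abundance at week 9, EpOME over vehicle (x axis, log scale), for the 10 genera with an unadjusted p under 0.05 (y axis). Points are ratios of the authors' group means, bars are 95% confidence intervals, and the vertical line marks equal means. The 9 lower genera lie left of the line and Muribaculum, at 1.72, lies right of it. No genus passed adjustment.

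None of the 6 fixed lists with a member in the table passed at week 9 when tested on summed abundance. The 13 listed producers of butyrate and other short-chain fatty acids, such as Butyricicoccus and the Lachnospiraceae NK4A136 group, summed to 7.33% with EpOME and 9.01% with vehicle. The difference was -1.69 points (95% CI -6.04 to 2.67, adjusted p = 0.644). Of these, 10 had lower and 3 higher means with EpOME, and 0 passed, over all genera and adjusted over the list alone. The 4 Bacteroidales of the mouse gut (Alistipes, Bacteroides, Muribaculum and Prevotellaceae UCG-001) all had higher means with EpOME and summed to 10.2% against 7.04% (adjusted p = 0.469). This sum passed only if its members were taken as independent (adjusted p = 0.0121). Of all 7 listed Bacteroidetes rows, 6 had higher means with EpOME and 1 lower, the Prevotellaceae NK3B31 group (ratio 0.792), and 0 passed. These rows summed to 22.3% with EpOME and 15.1% with vehicle. The 4 mucin degraders summed to 9.62% and 9.04% (adjusted p = 0.881), with 1 member lower when adjusted over the list alone, Mucispirillum. The 4 genera linked to colitis or colorectal tumours summed to 6.61% and 5.45% (adjusted p = 0.644), and the 3 Erysipelotrichaceae to 1.26% and 1.498% (adjusted p = 0.830). Lactobacillus was the only listed lactic acid bacterium (adjusted p = 0.644). In these last 3 lists, 0 members passed over all genera or adjusted over the list alone.

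The arms already differed in the samples labelled week 0, in the opposite direction for both main phyla. Firmicutes averaged 54.1% (SD 6.39) in the EpOME arm and 44.2% (SD 5.79) in the vehicle arm, a difference of 9.85 points (95% CI 4.62 to 15.1, adjusted p = 0.00615, Welch's test). Bacteroidetes averaged 44.1% (SD 6.42) and 53.0% (SD 5.28), a difference of -8.94 points (95% CI -14.0 to -3.86, adjusted p = 0.00615). The ratio of Firmicutes to Bacteroidetes means was 1.23 and 0.834, a log2 difference of 0.56 (95% CI 0.25 to 0.86, adjusted p = 0.00268). Verrucomicrobia averaged 0.281% (SD 0.113) and 1.42% (SD 1.62) and did not pass (adjusted p = 0.0719), although the lognormal approximation called them lower (adjusted p = 0.00234). That approximation also called Proteobacteria higher (adjusted p = 0.0430) and so 4 phyla in place of 2.

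At genus level, 4 of 51 genera passed at week 0, 3 higher and 1 lower in the EpOME arm. Prevotellaceae UCG-001, a Bacteroidales lineage, was lower, at 1.63% (SD 0.526) against 5.29% (SD 2.99), a ratio of 0.307 (95% CI 0.214 to 0.441, adjusted p = 0.0157). Alistipes, also of the Bacteroidales, was higher at 4.50% (SD 0.953) against 2.96% (SD 0.674), a ratio of 1.52 (adjusted p = 0.0151). Marvinbryantia, of the Lachnospiraceae, was higher at 0.750% (SD 0.322) against 0.306% (SD 0.128), a ratio of 2.45 (adjusted p = 0.0157). Ruminococcaceae UCG-014 was higher at 2.52% (SD 0.494) against 1.63% (SD 0.791), a ratio of 1.55 (adjusted p = 0.0379). In the authors' deposited table, 13 genera had a p under 0.05 at week 0, and 4 remained after adjustment. None of the 6 list sums passed at week 0, the smallest adjusted p being 0.255 for the mucin degraders and the Bacteroidales. Within lists, Alistipes was higher and Prevotellaceae UCG-001 lower both over all genera and adjusted over the list alone. The limma-moderated lognormal fit called 7 genera, and 3 list sums passed with members taken as independent.

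The vehicle samples were compared between weeks for the change in mice that received no epoxide. Lactobacillus, a lactic acid producer, rose from 9.45% (SD 3.98) to 22.5% (SD 9.58), a ratio of 2.38 (95% CI 1.72 to 3.30, adjusted p = 0.00187, Welch's test over 51 genera). Turicibacter rose 11.5-fold (adjusted p = 0.0358), from 0.0911% (SD 0.0818) to 1.05% (SD 1.25). Romboutsia and Clostridium sensu stricto 1, both of the Clostridia, rose 6.68-fold and 5.08-fold (adjusted p = 0.00546 and 0.00198). Prevotellaceae UCG-001 fell from 5.29% (SD 2.99) to 1.12% (SD 0.440), a ratio of 0.212 (adjusted p = 0.00187). A2, the [Eubacterium] fissicatena group and Ruminococcus 2 fell to 0.171, 0.241 and 0.322 of their week 0 means (adjusted p = 0.0156, 0.0158 and 0.0149). In all, 27 of 51 genera passed, 7 up and 20 down. Among the abundant genera, unclassified Lachnospiraceae fell from 6.64% to 3.03% (adjusted p = 0.000288) and the Lachnospiraceae NK4A136 group from 6.99% to 3.86% (adjusted p = 0.00187). The Prevotellaceae NK3B31 group fell from 5.87% to 1.94% (adjusted p = 0.00175).

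At phylum level in vehicle, Bacteroidetes fell from 53.0% to 43.0%, a difference of -10.0 points (95% CI -16.1 to -3.91, adjusted p = 0.0110). Actinobacteria rose from 0.437% to 1.05%, a ratio of 2.41 (adjusted p = 0.0110). Firmicutes averaged 44.2% and 49.6% and did not pass (5.39 points, 95% CI -0.471 to 11.2, adjusted p = 0.139), nor did Verrucomicrobia (adjusted p = 0.139). Firmicutes passed where a correlation of 0.5 was assumed between weeks (adjusted p = 0.0423), and Verrucomicrobia passed with the lognormal approximation, alone and with limma's moderation (adjusted p = 0.00566 and 0.00390). The log2 ratio of Firmicutes to Bacteroidetes rose by 0.47 (95% CI 0.10 to 0.84, adjusted p = 0.0161). By lists, the summed Bacteroidales fell from 11.7% to 7.04% (adjusted p = 0.0228), with 1 of 4 members lower, Prevotellaceae UCG-001, over all genera and adjusted over the list alone. Of all 7 listed Bacteroidetes rows, 2 were called lower, the other being the Prevotellaceae NK3B31 group, and 2 higher. Those higher were unclassified Muribaculaceae and the uncultured Bacteroidales bacterium, with ratios of 1.69 and 1.52 (adjusted p = 0.0376 and 0.0102 by Welch's test). The short-chain fatty acid producers summed to 12.7% and 9.01% (adjusted p = 0.0939), with 6 of 13 members lower over all genera and adjusted over the list alone. The Erysipelotrichaceae summed to 0.361% and 1.498% (adjusted p = 0.0542), with Turicibacter higher over all genera but 0 members adjusted over the list alone. The mucin degraders summed to 4.997% and 9.04% (adjusted p = 0.149) and the colitis-linked genera to 5.19% and 5.45% (adjusted p = 0.793). With list members taken as independent, 4 sums passed in place of 2.

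In the EpOME arm, Firmicutes fell from 54.1% to 40.0% between the weeks, a difference of -14.1 points (95% CI -19.9 to -8.29, adjusted p = 0.000477, Welch's test), and Bacteroidetes rose by 9.69 points (95% CI 1.81 to 17.6, adjusted p = 0.0381). Actinobacteria rose 3.24-fold (adjusted p = 0.0381), and Deferribacteres fell to 0.128 of their week 0 mean (adjusted p = 0.009998). The log2 ratio of Firmicutes to Bacteroidetes fell by 0.72 (95% CI -1.13 to -0.31, adjusted p = 0.00268). Unclassified Muribaculaceae, a family of Bacteroidales common in mice, rose from 2.39% (SD 0.427) to 8.37% (SD 6.96), a ratio of 3.50 (adjusted p = 0.0332). Enterorhabdus, an actinobacterium, rose 2.20-fold and Muribaculum 2.18-fold (adjusted p = 0.0279 and 0.0214). Lactobacillus rose from 10.1% (SD 3.37) to 19.7% (SD 6.77), a ratio of 1.94 (adjusted p = 0.00300), and Bacteroides 1.92-fold (adjusted p = 0.0277). Ruminococcaceae UCG-003 fell to 0.0663 of its week 0 mean, A2 to 0.115, Mucispirillum to 0.128 and Lachnospiraceae UCG-001 to 0.168 (adjusted p = 0.000128, 0.0332, 0.00671 and 0.00440). Butyricicoccus fell from 0.379% (SD 0.0891) to 0.0638% (SD 0.0240), with the smallest adjusted p of the 51 genera, 7.34e-06. In all, 27 genera passed, 6 up and 21 down, against 41 with the limma-moderated lognormal fit.

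The summed short-chain fatty acid producers fell in the EpOME arm from 15.9% to 7.33%, a difference of -8.54 points (95% CI -13.3 to -3.81, adjusted p = 0.00364). Of the 13 members, 5 were lower over all genera and adjusted over the list alone, including Butyricicoccus, Oscillibacter, Roseburia and the Lachnospiraceae NK4A136 group, which went from 9.29% to 3.02%. Among mucin degraders, Bacteroides and Muribaculum were higher and Mucispirillum lower, over all genera and adjusted over the list alone, and the sum went from 3.16% to 9.62% (adjusted p = 0.0917). Akkermansia averaged 0.281% (SD 0.113) and 4.07% (SD 7.18), a ratio of 14.5 (95% CI 4.96 to 42.2). It did not pass on the linear scale (adjusted p = 0.138 by Welch's test). The interval of the ratio is not reliable here, since the week 9 SD exceeds the mean. For Verrucomicrobia, almost entirely Akkermansia, the difference was 3.79 points (95% CI -1.04 to 8.61). Akkermansia passed as higher with the lognormal approximation, alone and with limma's moderation (adjusted p = 0.000463 and 8.58e-06). Of the 4 Bacteroidales in the fixed list, Bacteroides and Muribaculum were higher and Alistipes lower by both adjustments. The sum of this list was 8.83% and 10.2% (adjusted p = 0.507). All 7 listed Bacteroidetes rows summed to 16.0% and 22.3%, a change that was not tested. Over all genera 3 of these rows were called higher, including unclassified Muribaculaceae, and 1 lower. The colitis-linked genera summed to 6.19% and 6.61% (adjusted p = 0.724), with Bacteroides higher and Alistipes lower by both adjustments. The Erysipelotrichaceae summed to 0.387% and 1.26% (adjusted p = 0.0917), with 0 members passing. With members taken as independent, 4 sums passed in place of 2.

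The change between weeks was then compared between arms. The change of Firmicutes in the EpOME arm minus that in the vehicle arm was -19.5 points (95% CI -27.5 to -11.5, adjusted p = 0.000115, Welch's contrast of 4 groups), and that of Bacteroidetes was 19.7 points (95% CI 10.1 to 29.3, adjusted p = 0.000869). Among genera, 2 of 51 passed. Prevotellaceae UCG-001 differed by 4.26 points (95% CI 2.35 to 6.17, adjusted p = 0.0108), going from 5.29% to 1.12% with vehicle and from 1.63% to 1.72% with EpOME. Butyricicoccus differed by -0.157 points (95% CI -0.245 to -0.0686, adjusted p = 0.0243), going from 0.296% to 0.137% with vehicle and from 0.379% to 0.0638% with EpOME. A further 10 of the 12 genera at an unadjusted p under 0.05 did not pass, among them Bacteroides, Muribaculum and the Lachnospiraceae NK4A136 group (adjusted p = 0.123 for each). No list sum passed, the smallest adjusted p being 0.0790 for the Bacteroidales, of which 1 member was higher over all genera and 3 adjusted over the list alone. Of the mucin degraders, 2 members were higher adjusted over the list alone and 0 over all genera, and of the short-chain fatty acid producers 1, Butyricicoccus, was lower by both adjustments. Both of these phylum differences include the difference at week 0. With members taken as independent, 2 list sums passed. The count of genera was 17 with the lognormal approximation, and 17 where a correlation of 0.5 was assumed between weeks.

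The direction of change was shared between arms for most genera. Of 51 genera, 43 had ratios of week 9 to week 0 means on the same side of 1, 15 up and 28 down. Across genera, which are not independent replicates, the log2 ratios correlated with r = 0.82 and rho = 0.84. Both arms called 3 genera up and 16 down, where independent lists would share 0.824 and 8.24. Lactobacillus, Enterorhabdus and unclassified Muribaculaceae were the 3 called up in both.

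**Figure D3:**
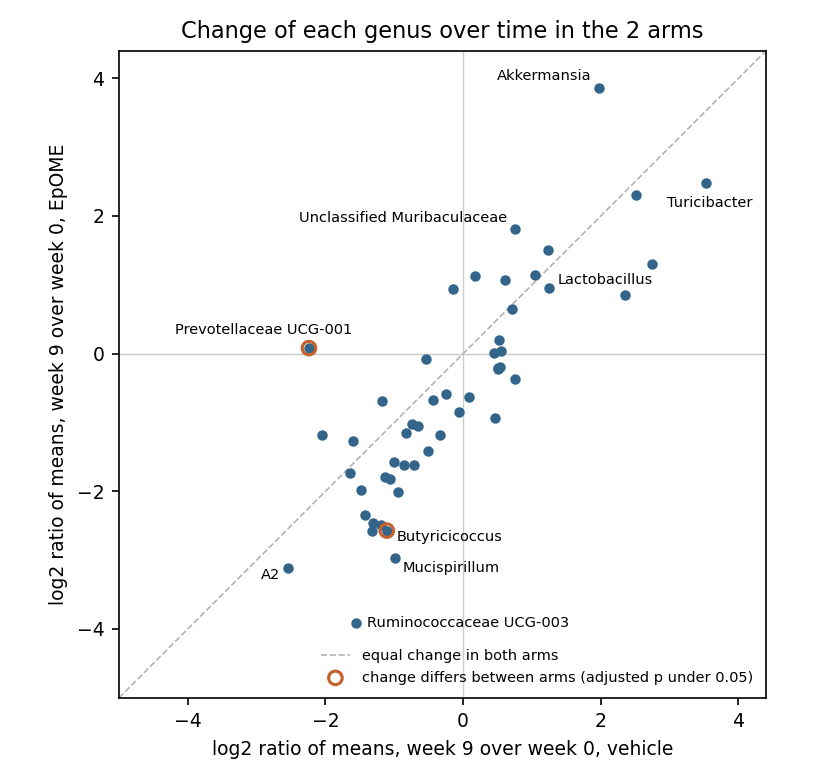
The log2 ratio of week 9 to week 0 mean relative abundance of each of 51 genera, in vehicle (x axis) and EpOME (y axis). Points are genera, the dashed line marks equal change, and orange rings mark Prevotellaceae UCG-001 and Butyricicoccus, whose change in percentage points differed between arms. Most points lie in the lower left and upper right, with 43 of 51 genera on the same side of 0 in both arms.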

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

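The tests of explanations in this part, and the interaction of the Firmicutes to Bacteroidetes ratio, were chosen after the results were seen. Comparing the change over time between arms for phyla and genera was planned, with another test statistic.

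The arms differed in how they changed between weeks for 5 results. Those for Firmicutes, Bacteroidetes and their ratio are not independent of each other, since these phyla made up most of every community. The change in EpOME minus that in vehicle was -19.5 percentage points for Firmicutes (adjusted p = 0.000115) and 19.7 for Bacteroidetes (adjusted p = 0.000869). It was -0.157 points for Butyricicoccus (adjusted p = 0.0243), 4.26 points for Prevotellaceae UCG-001 (adjusted p = 0.0108), and -1.19 for the log2 ratio of Firmicutes to Bacteroidetes (adjusted p = 0.000315).

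Part of these differences lay at week 0, where Firmicutes were 9.85 points higher in the EpOME arm, and for Prevotellaceae UCG-001 nearly all of it did, with a difference between arms of -3.66 points at week 0 and 0.598 at week 9 (adjusted p = 0.0157 and 0.306). Against chance at week 0 there is only the adjusted p-value of that comparison (0.00615), which assumes independent samples. No separate test was made of such chance. A chance difference that shrank back would leave the arms nearly equal at week 9. Firmicutes instead differed by -9.64 points (confidence interval -16.0 to -3.27) and Bacteroidetes by 10.8 (2.29 to 19.2), opposite in sign to week 0. If samples were independent, these values argue against shrinking back as the whole cause for both phyla. For Prevotellaceae UCG-001, whose week 9 interval ran from -0.0996 to 1.30 points, shrinking back stays open. Butyricicoccus differed by 0.0834 points at week 0 (0.00783 to 0.159) and by -0.0732 at week 9 (-0.123 to -0.0230), also opposite in sign. These unadjusted intervals go against shrinking back as its whole cause. Butyricicoccus did not pass adjustment at either week (adjusted p = 0.168 and 0.132 by Welch's test), so for this genus the question is not settled. The tables argue against an exchange of the arms' week 0 columns, since in the authors' deposited table all 61 week 0 p-values equalled Student's test with 13 samples in the control and 11 in the EpOME column, and 0 did with these numbers exchanged (relative tolerance 1e-06). Untested and open are single mislabelled samples, shared cages or littermates within an arm, an effect of sequencing run at 1 week, and an effect of the epoxide, which may have begun before the week 0 samples, since the labels give no cages, runs or dosing schedule.

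Relative abundances sum to 100, so a gain of Bacteroidetes alone would lower every other taxon by 1 factor, 0.811 at week 9. For Firmicutes the ratio of means was 0.806, and since the closed sum nearly fixes this value, a loss of Firmicutes and a gain of Bacteroidetes cannot be told apart. For Deferribacteres the upper bound of the ratio was 0.688, under that factor. The factor was computed from group means and taken as exact, although the Bacteroidetes difference had a confidence interval of 2.29 to 19.2 points. The comparison therefore cannot decide whether dilution was the whole cause of the lower share of Deferribacteres. Of the 40 Firmicutes genera, 5 had intervals below the factor and 4 above it, where 2 would be expected if the factor were exact. Other causes of the lower share of Deferribacteres were not tested, and this phylum was chosen because it was low.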

How the results depend on the processing

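The alternatives here were chosen after seeing the data, except the filter on taxa under 0.1%, which was planned. Of 66 counts, list totals and ratios recomputed, 51 stayed on the same side of the threshold or within 1.5 times. Another 10 moved further, and 5 went from 0 to some calls. Counts have no direction, so this comparison does not show whether directions were kept. With the filter, phyla passing at week 9 went from 3 to 1: Deferribacteres were removed, and Bacteroidetes, adjusted over fewer phyla, reached an adjusted p of 0.0540, as they did with limma's variance moderation. The other 72 of 73 calls of single taxa passed with the same direction in every alternative that tested them. Taxa that passed only in an alternative include Firmicutes in vehicle over time (0.0423 with a correlation of 0.5) and Akkermansia in EpOME over time (0.000463 with the lognormal approximation). With the lognormal approximation, alone and with limma's moderation, phyla at week 0 went from 2 to 4 and 4, genera at week 9 from 0 to 6 and 6, and genera in the interaction from 2 to 17 and 16. With moderation, genera at week 0 went from 4 to 7, and those changed over time in EpOME from 27 to 41. The approximation made calls in 8.8% of simulations without any change, or 24.4% with gamma values, against 2% for Welch's test. These simulations used the vehicle group's SDs for both arms. A correlation of 0.5 between weeks took the genera in the interaction from 2 to 17. With list members independent, list sums passing went from 0 to 1 at week 9, 0 to 3 at week 0, 2 to 4 in vehicle over time, 2 to 4 in EpOME over time and 0 to 2 in the interaction, since the SD of each sum is then smaller. For the other moves the cause was not tested. No paired analysis was possible because the columns carry group means and no replicate numbers. Not run, since they need values per sample, were the planned permutation tests, pseudocounts, centred log-ratios, rank statistics, community distances, diversity indices, leaving out samples and other splits of the samples. Depth is unknown, so what it limits for rare genera cannot be stated.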

Other observations

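The tests reported in this part were chosen after the values were seen. The 10 genera whose row names hold Lachnospiraceae or Ruminococcaceae, a set picked by name after its values were seen and not tested for enrichment, all had lower means with EpOME than with vehicle at week 9. Their means summed to 8.39% and 11.8%, against 22.6% and 18.2% at week 0. Of these genera 0 passed adjustment at week 9, 4 had an unadjusted p under 0.05, and the median log2 ratio was -0.57. Lower means with EpOME were common more widely, in 36 of all 51 genera and 32 of 40 Firmicutes genera. The 8 Firmicutes genera with higher means were all outside this set, which does not hold every genus of these families. Marvinbryantia, of the Lachnospiraceae, was among these exceptions, with a ratio of 1.48. Others were the [Eubacterium] fissicatena group, Ruminococcus 2 and Butyrivibrio, with ratios of 1.48, 1.57 and 1.15, and none of these passed either. The lower means of the set thus do not describe the Lachnospiraceae as a whole. Between the weeks, 6 of the 10 means were lower and 4 higher with vehicle, and 9 were lower and 1 higher with EpOME. After adjustment, 6 passed as lower with vehicle, and 7 as lower and 1 as higher with EpOME.

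The genus table's row for taxa under 0.1% held a large part of each community: 38.0% with vehicle and 36.9% with EpOME at week 0, and 32.2% and 35.4% at week 9. Subtracting the listed genera from each phylum places 83.7% and 76.2% of this row in Bacteroidetes at week 0, and 86.7% and 88.8% at week 9. With EpOME at week 9, 31.5 of the 53.8 points of this phylum thus lay outside its 7 listed rows. The table does not say whether this row also holds reads assigned to no genus, so it is not known how much of it is rare genera.

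The deposited SDs were larger relative to the means at week 9. The coefficient of variation was higher at week 9 than at week 0 in 40 of 51 genera with vehicle and in 47 of 51 with EpOME. Its median went from 0.436 to 0.616 with vehicle and from 0.385 to 0.745 with EpOME. Means were also lower at week 9 in 30 of 51 genera with vehicle and in 34 with EpOME. Whether the larger relative SDs reflect these lower means or more variation between mice was not tested. Across genera, which are not independent, the log2 ratios of EpOME to vehicle at week 0 and at week 9 correlated with r = -0.0011, and 19 of 51 genera had the same direction.

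Akkermansia had a mean of 4.07% with a deposited SD of 7.18 with EpOME at week 9. A hypothesis is that few samples held most of it. From the mean, the SD and 11 samples that cannot be negative, the highest sample held at least 34.9% of the group's sum, where an even share is 9.09%. It thus reached at least 15.6% of its community, and the other samples averaged at most 2.91%. With vehicle at week 9 the same bound was 18.3% of the sum, where an even share is 7.69%. The bound of 34.9% shows that the sum with EpOME was spread unevenly over the samples. Whether differences between mice or a technical cause lay behind this cannot be settled from group means.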
